A study of Sus scrofa with 5 samples.

How the data were processed

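Nuclei were isolated from 80 mg of thoracic and lumbar dorsal root ganglion per sample, from 5 male Landrace pigs, per the labels' protocols. The protocols differed in detergent and in the separation of nuclei from debris (density gradient, or magnetic or fluorescence-activated enrichment with an antibody against the neuronal protein NeuN). Libraries were made with the 10x Genomics Next GEM chemistry for 3' ends. Cell Ranger 6.0.1, Seurat and the pig genome build Sscrofa11.1 are named without roles, per the submitters' processing notes. The authors deposited 1 table of raw counts of unique molecular identifiers (UMIs), 30477 genes by 2189 nuclei, with no normalization. A filter on nuclei before deposit is not given in the sources used here; the lowest total was 501 UMIs. Of the rows, 14012 carried an Ensembl identifier, 773 of which received a symbol from a table of gene names, and 6124 rows held no count.

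Barcodes ended in 6 numbers, read as 6 libraries. Nothing tied these to the 5 pigs or to a protocol, so the table was treated as 1 pooled sample, the fallback fixed before the data were examined. The planned edgeR and DESeq2 tests over pigs were therefore not used, and no p-value was computed. The library was used as a technical batch only. Depth per library ranged from 760816 UMIs in library 2 to 4910023 in library 6. Of all UMIs, 16.8% came from 30 nuclei above 50000 UMIs, in libraries 2, 4 and 6.

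Every nucleus had at least 200 genes, so that filter removed none. Scrublet, run in scanpy, called 1 nucleus a doublet (0.046%), below the 0.5% fixed as the least share at which its calls would be used, and no nucleus was removed. Doublets were weighed for the deepest nuclei instead: none of 18 C-fibre-like and 9 large-fibre-like nuclei above 50000 UMIs carried the other side's 10 named genes, summed, above 0.5 times that side's level. The highest sums were 320 CPM in a C-fibre-like nucleus (other side 1133 CPM) and 912 CPM in a large-fibre-like one (other side 2462 CPM). Those genes were picked as most different between the sides in these data. An uneven mixture would also stay below the limit, so doublets are not excluded. Mixtures within the C-fibre-like classes were not tested, and the deepest C_PEP-like nucleus held 194 of the 460 TRPM8 UMIs and 86 of the 313 OSMR UMIs of its class. Counts were normalized to 10000 per nucleus and log-transformed. The 2000 most variable genes were taken, and the members of 14 functional lists were left out of them (1890 features remained), so that differences in list genes between clusters were not built in. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1.0, which gave 21 clusters. The libraries were not integrated.

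Cell type markers were fixed before the data were examined. They included PVALB, ETV1, RUNX3, HEG1, NTRK3 and WNT7A (proprioceptors), NTRK3, NTRK2, SLC17A7, ESRRG, CALB1, MAF and KCNS1 (A-fibre touch neurons), TAC1, TRPV1 and ADCYAP1 (C_PEP), LPAR3, GFRA2, PLXNC1, LPAR5 and P2RX3 (MRGPRD neurons), SLC17A8, TAFA4, GFRA2, ZNF521, CASQ2, CDH9 and TH (C-fibre touch neurons), SST, NPPB, OSMR, IL31RA, HTR1F, CYSLTR2, JAK1 and NTS (SST_OSMR), and TRPM8, FOXP2, CDH8, RXFP1, PENK and TAC1 (C_TRPM8). Further lists covered A-fibre peptidergic and MRGPRX neurons and 10 kinds of other cells. CALCA, CALCB, MRGPRD, the MRGPRX genes and NECAB2 were not analysed here, since no row carried those symbols. The score of a list in a cluster was the mean log2 ratio of CPM, with 10 CPM added, against the rest of the same library. A cluster took the name of its best list from a score of 0.75, with a lead of 0.5 over the next class, at least 3 detected markers and no more markers of another class than of its own among its top 10 genes. The scoring rule and its thresholds were set after the clusters had been seen. Proprioceptors and A-fibre touch neurons were joined as large-fibre-like, and the markers of MRGPRD neurons and C-fibre touch neurons scored together in the same clusters, joined as the GFRA2_LPAR3 class.

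UMIs were summed over the nuclei of a class and given as counts per 1000000 UMIs of the class (CPM) with exact Poisson intervals. Ratios of CPM carry the exact conditional binomial interval of the ratio of Poisson rates, and shares the exact Clopper-Pearson interval, all at 95% and for counting error only. Nuclei are not replicates, and these intervals say nothing of the spread between pigs. A count of 0 was set to a floor of 3 counts over the class. Ratios were computed for genes with at least 50 UMIs over both sides. Within-library ratios needed 10 nuclei per side and 10 UMIs, with 0.5 counts added on each side.

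Named genes followed a rule fixed beforehand. Among members of the functional lists that were not naming markers of a class compared, the 10 largest ratios in each direction whose interval excluded 1 were named, or 3 higher and 2 lower for a class against the rest. One gene that the rule named is not reported here. A set of pain and itch genes was named whatever its values. Members given as examples of a list were chosen after their values were seen. The lists held sodium channels, potassium and HCN channels, calcium channels, transduction channels, ligand-gated channels, inhibitory receptors, pronociceptive receptors, cytokine and growth factor receptors, neuropeptides, transmitter handling, axonal and pump genes, transcription factors, injury and activity genes and the mitochondrial genome (551 genes, 505 in the table). Each list is summarised by its median log2 ratio without naming markers and by the percentile of that median among 10000 random lists matched on expression in 20 bins. The percentile describes these libraries and is not a test.

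The ratios and their intervals were tested on simulated data, with Poisson counts for the real genes and 200 genes changed by known folds. For C-fibre-like against large-fibre-like nuclei, 97.8% of genes changed 2-fold and 100% of those changed 4-fold were recovered in the right direction (12944 genes run). For SST_OSMR-like against other C-fibre-like nuclei these shares were 90.9% and 97.9% (11940 genes run). The simulated counts followed the Poisson model that the intervals assume, with fixed classes and no spread between nuclei or libraries. Such rates check the calculation and say nothing of the error from that spread or from the clustering. Alternatives covered scaling, the count minimum, thinning, the mean over nuclei, clustering features and resolution, a minimum of 1000 genes, count splitting, single libraries left out, the deepest nuclei left out, clustering within libraries and the naming score. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.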

Results

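Dorsal root ganglia hold the cell bodies of the sensory neurons that carry touch, temperature, itch and pain signals from the body to the spinal cord. Nuclear RNA was sequenced nucleus by nucleus from thoracic and lumbar ganglia of 5 male Landrace pigs, a single group with no treatment, after nuclei isolation by protocols that differed in lysis and in how neuronal nuclei were enriched. The count table held 2189 nuclei and 17277376 unique molecular identifiers (UMIs), with a median of 4565 UMIs per nucleus and a range from 501 to 338372. Barcode endings separated 6 libraries, and nothing in the table tied these to the 5 pigs. The table was therefore 1 pooled sample without replicates: no test was run, and every 95% interval covers counting error only, not the spread between animals.

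The libraries differed strongly in size and depth. Library 3 held 805 nuclei with a median of 3971 UMIs, library 1 held 682 with 2647, library 5 held 331 with 5649 and library 6 held 283 with 12038. Libraries 4 and 2 were small, with 75 and 13 nuclei and medians of 10422 and 676 UMIs. Median shares of UMIs from the mitochondrial genome were 18.5% in library 3, 4.08% in library 1, 0.114% in library 5 and 0.0605% in library 6. Pooled ratios therefore mix libraries that differ in this way, and ratios within libraries are given for some genes.

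Which kinds of sensory neuron were captured was asked first, since the study set out to describe their diversity. Nuclei resembling peptidergic C-fibre neurons (C_PEP-like) made up 26.8% of the table (586 of 2189 nuclei, exact binomial interval 24.9 to 28.7%). Those resembling large myelinated touch and muscle afferents (large-fibre-like) made up 23.9% (523 nuclei, 22.1 to 25.7%). Smaller shares fell to SST_OSMR-like neurons, named after itch-related receptors and peptides (9.23%, 8.05 to 10.5%), to C_TRPM8-like neurons, named after the cold channel (9.59%, 8.39 to 10.9%), and to a class called GFRA2_LPAR3 here (9.69%, 8.48 to 11.0%). Other ways of clustering, naming or leaving out nuclei moved these shares beyond their counting intervals: the lowest and highest were 18.8 and 43.4% for C_PEP-like, 14.8 and 26.7% for large-fibre-like, 2.74 and 13.1% for SST_OSMR-like and 6.07 and 23.4% for C_TRPM8-like nuclei, and 7.37 and 12.3% for the GFRA2_LPAR3 class. The GFRA2_LPAR3 class carried the markers of non-peptidergic MRGPRD neurons and of C-fibre touch neurons together, and these could not be separated. No cluster took the name of A-fibre peptidergic or MRGPRX neurons. CALCA, MRGPRD and the MRGPRX genes were not analysed here under those symbols.

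The identity of each class rested on markers. ADCYAP1 marked C_PEP-like nuclei, at 255.3 counts per 1000000 UMIs (CPM) there against 74.9 CPM or less in the other named classes. Its level in C_PEP-like nuclei ranged from 103 CPM in library 6 to 1175 CPM in library 4. TAC1 and TRPV1, markers of the same list, were highest in other classes over all libraries. TAC1 stood at 2475 CPM in C_PEP-like but 4119 CPM in SST_OSMR-like nuclei. TRPV1 stood at 40.1 CPM in C_PEP-like but 103 CPM in C_TRPM8-like nuclei. IL31RA stood at 1594 CPM in SST_OSMR-like and 234 CPM in C_PEP-like nuclei (75.9 CPM in library 1 but 316 CPM in libraries 5 and 6), GFRA2 at 442 CPM in the GFRA2_LPAR3 class, TRPM8 at 767 CPM in C_TRPM8-like nuclei, and PVALB at 243 CPM (32.1 CPM in library 5 to 577 CPM in library 1) and SLC17A7 at 49.4 CPM in large-fibre-like nuclei. Shares by class depended on the library. With library 2 and its 13 nuclei set aside, C_PEP-like nuclei ranged from 13.8% of library 1 to 43.2% of library 5, and C_TRPM8-like nuclei from 0.733% of library 1 to 15.7% of library 3. Without library 3 the C_TRPM8-like share was 6.07%. Another 456 nuclei (20.8%, 19.2 to 22.6%) stayed unnamed, among them a shallow cluster of 302 nuclei led by TRPM8 (median 1437 UMIs), 296 of them from library 1. A naming threshold set after seeing the data kept that cluster out of the C_TRPM8-like class. Most clusters came from 1 library or from libraries 5 and 6 together. Isolation protocol, enrichment and the depth of each library can set these shares.

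**Figure D1:**
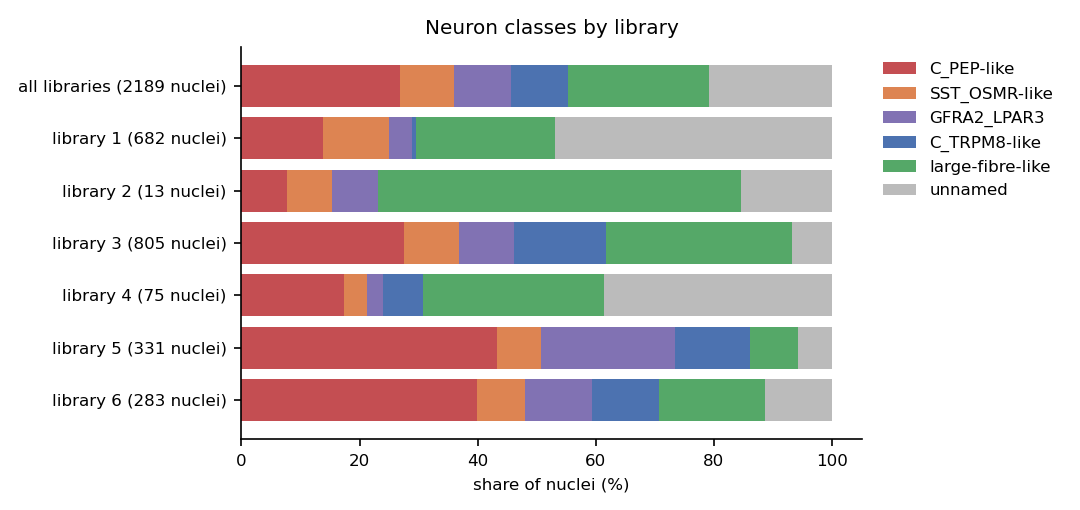
Share of nuclei (percent, x axis) in each neuron class for the pooled table and for each of the 6 libraries, with the number of nuclei beside each bar. C_PEP-like nuclei made up 43.2% of library 5 and 13.8% of library 1, where 46.9% of nuclei stayed unnamed.

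C-fibre-like nuclei (the C_PEP-like, SST_OSMR-like, GFRA2_LPAR3 and C_TRPM8-like classes, 1210 nuclei) were set against the 523 large-fibre-like nuclei. C-fibre-like nuclei carried more transcripts of the tetrodotoxin-resistant sodium channels SCN10A and SCN11A, of several TRP channels and of the kappa opioid receptor OPRK1. Large-fibre-like nuclei carried more transcripts of the fast potassium channels KCNA1 and KCNC1 and of the release protein CPLX1. SCN10A stood at 659 CPM in C-fibre-like and 70.2 CPM in large-fibre-like nuclei, 9.39-fold higher (interval 8.34 to 10.6), and SCN11A at 404 against 43.7 CPM, 9.25-fold higher (7.96 to 10.8). These ratios pool the classes, and not every class shared them. Over all libraries, C_TRPM8-like nuclei had only 60.8 CPM of SCN10A and 31.2 CPM of SCN11A. The genes named here kept their direction in every library that gave a value.

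Among the channels higher in C-fibre-like nuclei, TRPM3 was abundant (1122 against 132 CPM, 8.48-fold, 7.78 to 9.26). TRPC6 (13.7-fold) and TRPC4 (8.33-fold) were rarer, at 37.0 and 47.0 CPM. The potassium channel genes KCNH6 (15.4-fold, 8.02 to 33.9) and KCNG2 (10.1-fold, 7.14 to 14.6) also belonged to this side, as did the alarmin gene IL33 (10.7-fold, 6.69 to 18.2). KCNH6 in SST_OSMR-like nuclei (2.08 CPM) and IL33 in the GFRA2_LPAR3 class (6.59 CPM) were near the large-fibre-like levels (2.21 and 4.42 CPM). TRPC6 stood at 132.1 CPM in SST_OSMR-like and 26.05 CPM in C_PEP-like nuclei. With 8 UMIs in the GFRA2_LPAR3 class, TRPC6 was there near the large-fibre-like level of 2.701 CPM. TRPC4 in the GFRA2_LPAR3 class (7.367 CPM) was likewise near its large-fibre-like level (5.647 CPM). OPRK1 showed the largest ratio, 31.1-fold, but only 3 UMIs on the large-fibre side gave it a wide interval of 10.5 to 152. It stood at 44.6 CPM in C_PEP-like nuclei and at 2.08 to 3.88 CPM in the other C-fibre-like classes. POU4F1 rested on 50 UMIs against 1 and had an interval of 3.14 to 738.

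In the opposite direction, KCNA1 stood at 160 CPM in large-fibre-like and 4.95 CPM in C-fibre-like nuclei, 32.4-fold apart (24.6 to 43.5), with log2 ratios of C-fibre-like over large-fibre-like from -4.49 to -3.89 within libraries. KCNC1 (103 against 7.10 CPM) and KCNQ3 (341 against 25.0 CPM) followed, and then the transcription factor genes ONECUT1 (13.2-fold, 9.97 to 17.8) and SHOX2 (10.3-fold, 6.94 to 15.8). C_TRPM8-like nuclei had 28.85 CPM of KCNC1 and 28.1 CPM of ONECUT1, more than the other C-fibre-like classes. CPLX1 was 7.81-fold higher on the large-fibre side. S1PR3, GABRD and CHRNA5 were 8.71-fold, 8.19-fold and 7.58-fold higher there at 16.4 CPM or less. Single libraries changed the size of some ratios: KCNG2 rose from a log2 ratio of 3.33 to 4.27 without library 1, IL33 went from 3.42 to 4.03 without library 1 and to 2.76 without library 3, and KCNQ3 went from -3.77 to -3.18 without library 4. Over all alternatives, the log2 ratios that moved by more than 1.5 times ran from 3.84 to 5.51 for OPRK1, 2.15 to 4.99 for POU4F1, 3.33 to 4.61 for KCNH6, 3.48 to 4.39 for TRPC6, 2.76 to 4.36 for IL33, 2.97 to 4.27 for KCNG2, 2.87 to 4.08 for SCN10A and 2.60 to 3.76 for SCN11A. On the large-fibre side they ran from -5.14 to -3.69 for KCNA1, -4.14 to -2.57 for KCNQ3, -4.16 to -3.04 for ONECUT1, -3.96 to -2.43 for S1PR3, -4.59 to -2.94 for GABRD and -3.62 to -2.55 for CHRNA5. Those of TRPM3, TRPC4, KCNC1, SHOX2 and CPLX1 moved less.

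**Figure D2:**
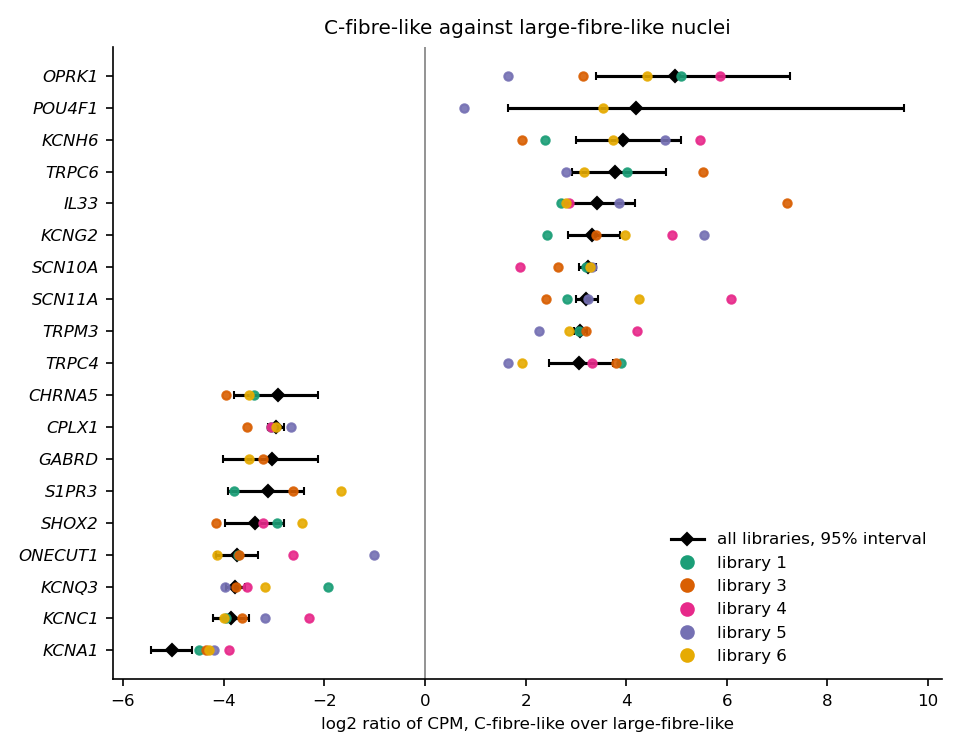
Log2 ratio of CPM, C-fibre-like over large-fibre-like nuclei (x axis), for genes named by the fixed rule (y axis, 1 of them not shown). Black diamonds give all libraries with the exact 95% counting interval, and coloured points the ratio within each library, which lay on the same side of 0 as the pooled ratio for every gene.

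Each functional list was summarised by its median. In this comparison, for every list except the mitochondrial genome, the 95% interval of this median over its genes included 0. Inhibitory receptors had a median log2 ratio of 0.54 (20 genes), at percentile 99.98 of 10000 random lists matched on expression, with OPRM1 at 302 against 44.0 CPM. Calcium channels (0.48, percentile 99.9), transcription factors (0.40, percentile 100) and sodium channels (0.33, percentile 95.3, but 0.97 as mean CPM over nuclei and 1.02 after thinning every nucleus to 1000 UMIs) leaned the same way, and RUNX1 (314 against 63.1 CPM) and CACNA1C (518 against 124 CPM) were examples. Over the alternatives these medians ran from 0.0815 to 1.10 for inhibitory receptors, 0.38 to 0.84 for calcium channels, 0.0777 to 0.49 for transcription factors and 0.24 to 1.02 for sodium channels. Transduction channels had a pooled median of 0.37 but a median of -0.07 from within-library means. Axonal and pump genes leaned to the large-fibre side (-0.43, percentile 2.37, with -0.66 to -0.22 over the alternatives), with NEFH at 2695 against 659 CPM, as did ligand-gated channels (-0.33, percentile 3.44, but 0.09 after thinning and 0.10 with count splitting, where nuclei are clustered on 1 part of their UMIs and compared on the other), with GRIA4 at 428 against 72.6 CPM. Potassium and HCN channels split between the sides (-0.11, percentile 27.4, with 0.0760 in nuclei with at least 1000 genes and 0.14 with each library clustered alone).

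For the other lists the medians for C-fibre-like over large-fibre-like nuclei were 0.11 for pronociceptive receptors, 0.13 for cytokine and growth factor receptors, 0.10 for transmitter handling and -0.17 for neuropeptides. Among the neuropeptides GAL stood at 75.5 CPM in C-fibre-like against 10.3 CPM in large-fibre-like nuclei, although its log2 ratio was -0.29 in library 5, while CHGA was lower at 14.4 against 57.0 CPM. Injury and activity genes gave -0.29, but 0.10 from within-library means, 0.05 without library 1, 0.49 at Leiden resolution 0.5 and -0.935 with count splitting. Neuropeptides likewise gave 0.19 from within-library means and 0.48 without library 1, and transmitter handling gave -0.05 as mean CPM over nuclei and -0.26 without library 6, so no direction held for these lists. Pronociceptive receptors gave -0.01 without library 1, -0.24 in nuclei with at least 1000 genes and 0.97 after thinning, and cytokine and growth factor receptors gave -0.00323 in nuclei with at least 1000 genes. The mitochondrial genome gave 0.23, which became -0.28 without library 3, 0.00291 without library 4, 0.44 without library 5 and 0.50 without library 6, and ran up to 1.14 with count splitting.

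SST_OSMR-like nuclei (202) were then set against the other C-fibre-like nuclei (1008) to ask how this putative itch class differs from its neighbours. They carried more transcripts of the peptide gene NMB, of the receptor genes NPY2R and HRH2, and of the cation channel genes TRPC6 and P2RX5. They carried fewer transcripts of the mechanically gated channel PIEZO2, of the potassium channel KCNH1, of the delta opioid receptor OPRD1 and of T-type calcium channels. NMB stood at 913 against 62.1 CPM, 14.7-fold higher (13.4 to 16.2; log2 ratios of 1.65 to 3.49 within libraries, below the pooled 3.88), and PIEZO2 at 44.2 against 681 CPM, 15.4-fold lower (12.4 to 19.3). The GFRA2_LPAR3 class carried that PIEZO2 level (2067 CPM), while C_PEP-like nuclei had 167 CPM and C_TRPM8-like nuclei 35.1 CPM, less than SST_OSMR-like ones. The median log2 ratio of all genes was -0.18 in this comparison, so small ratios are to be read against that shift.

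Beside NMB, the peptide-processing enzyme gene PCSK2 (964 against 185 CPM, 5.21-fold) and the transcription factor genes ETV1 (9.10-fold, 8.26 to 10.0) and KLF5 (4.02-fold, 3.47 to 4.65) were higher in SST_OSMR-like nuclei. The receptor genes HRH2 (6.03-fold) and NPY2R (10.9-fold, 6.74 to 17.9) were low in both groups, at 32.8 and 30.7 CPM on the higher side, and a single deep nucleus held 18 of the 59 NPY2R UMIs. TRPC6 was 7.74-fold higher (6.32 to 9.51), P2RX5 4.70-fold, KCNA3 4.78-fold and KCNA4 4.32-fold. KCNA4 was the exception among the 20 genes named here, since its log2 ratio was -1.77 in library 6 and its pooled ratio fell from 2.11 to 0.98 without library 1. P2RX5 turned to -0.62 with count splitting.

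Among the genes lower in SST_OSMR-like nuclei, KCNH1 stood at 7.80 against 244 CPM, 31.3-fold lower (18.9 to 56.0). BCL11A (26.7-fold lower, 11.4 to 82.4), KCNH6 (19.5-fold) and OPRD1 (19.4-fold) rested on 4 or 5 UMIs in SST_OSMR-like nuclei, as did BDKRB2 (13.6-fold) and OPRK1 (13.1-fold, 5.06 to 48.5). CACNA1G and PRDM8 had 1 UMI each there, with intervals of 3.25 to 743 and 2.99 to 685. CACNA1I had 0 UMIs there against 188, 13.1-fold lower with the 0 set to the floor of 3 counts over the class. The exact upper limit of its level there was 1.92 CPM, above the 1.56 CPM of that floor. Single classes held most of some of these transcripts on the other side: CACNA1I in the GFRA2_LPAR3 class (167 of 188 UMIs), and OPRK1 (238 of 251) and BDKRB2 (249 of 261) in C_PEP-like nuclei. Without library 6 the log2 ratio of TRPC6 was 3.63, that of KCNH1 was -5.94 and that of OPRD1 was -5.88. PRDM8 gave -2.02 without library 1 and -3.37 without library 3. These sizes depended on where the border with C_PEP-like nuclei was drawn. At Leiden resolution 1.5 the log2 ratio of KCNH1 went from -4.97 to -1.66, that of OPRK1 from -3.71 to -0.23, that of BDKRB2 from -3.77 to -0.88 and that of CACNA1G from -4.22 to -0.71, while TRPC6 rose from 2.95 to 4.79. Over all alternatives, log2 ratios ran from -6.34 to -1.61 for KCNH1, -5.09 to -1.28 for BCL11A, -4.68 to -1.55 for KCNH6, -5.88 to -1.78 for OPRD1, -5.19 to -0.59 for CACNA1G, -4.64 to -1.02 for PRDM8, -4.11 to -2.47 for PIEZO2, -4.32 to -0.88 for BDKRB2, -4.70 to -0.18 for OPRK1 and -4.34 to -0.69 for CACNA1I. Among the higher genes they ran from 2.47 to 4.05 for NMB, 2.69 to 4.40 for NPY2R, 1.55 to 4.79 for TRPC6, 1.78 to 3.11 for HRH2, 1.32 to 2.56 for KCNA3, 0.60 to 2.49 for KCNA4 and 1.19 to 2.37 for KLF5. Those of ETV1 and PCSK2 moved by less than 1.5 times.

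**Figure D3:**
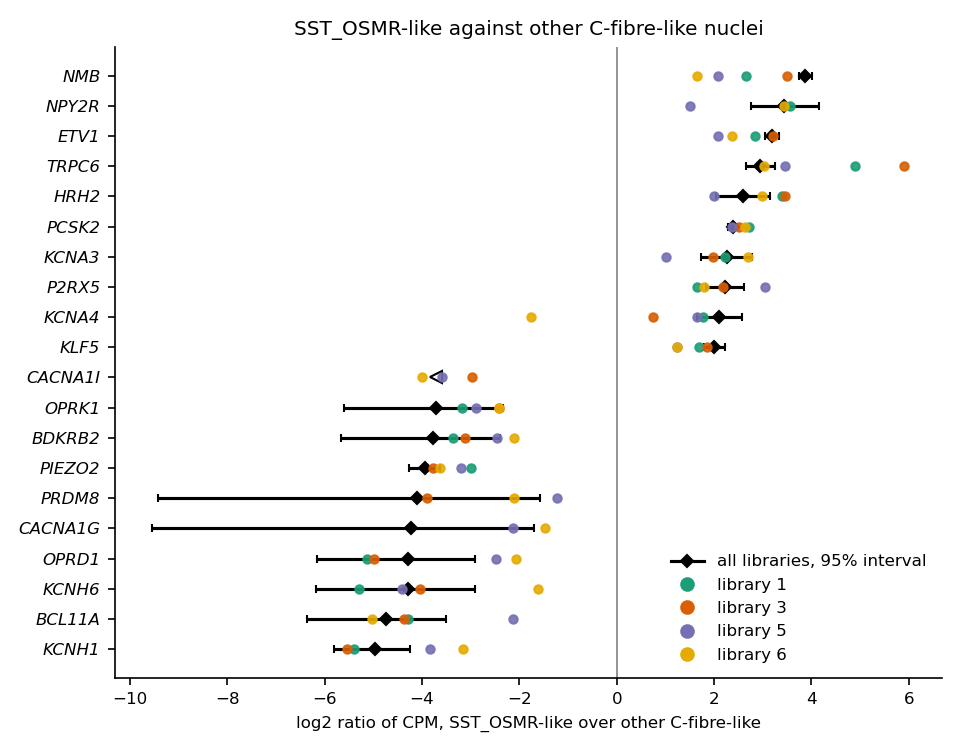
Log2 ratio of CPM, SST_OSMR-like over the other C-fibre-like nuclei (x axis), for the 20 genes named by the fixed rule (y axis), with exact 95% counting intervals for all libraries (black) and the ratio within each library (coloured). The open triangle for CACNA1I is the ratio with its 0 UMIs set to a floor of 3 counts. KCNA4 was the exception in direction, at -1.77 in library 6.

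By list, neuropeptides gave a median log2 ratio of 0.87 for SST_OSMR-like over other C-fibre-like nuclei, which shrank to 0.09 from within-library means and turned to -0.0483 with count splitting. Calcium channels (-1.02, percentile 0 of the random lists), pronociceptive receptors (-0.87, percentile 0.30), transcription factors (-0.71, percentile 0.04) and transduction channels (-0.70, percentile 0.02) were lower in SST_OSMR-like nuclei. The intervals over genes included 0 for neuropeptides and for sodium channels (-0.74, percentile 1.42, but -0.10 with count splitting). They also included 0 for inhibitory receptors, axonal and pump genes, transmitter handling, and injury and activity genes. CACNA1A (12.5 against 147.6 CPM) and TRPA1 (40.6 against 129 CPM) were examples of lower genes, whereas SCN11A went the other way at 1024 against 275 CPM. Ligand-gated channels (-0.69, percentile 0.45), potassium and HCN channels (-0.57, percentile 0.06) and cytokine and growth factor receptors (-0.51, percentile 0.21) also lay below 0. Injury and activity genes (-0.41, percentile 27.4) did not stand apart from random lists. Inhibitory receptors (-0.52), axonal and pump genes (-0.41) and transmitter handling (-0.13) gave 0.15, 0.03 and 0.02 as mean CPM over nuclei, so their direction did not hold. The mitochondrial genome gave 0.82, with 1.12 without library 1, 1.32 without library 3, 0.65 without library 5, 0.43 without library 6 and 2.02 with count splitting. With a finer clustering (Leiden resolution 1.5) transduction channels moved to 0.05, ligand-gated channels to 0.000419, pronociceptive receptors to 0.09, cytokine and growth factor receptors to 0.09 and the mitochondrial genome to -0.33. The class then held 287 nuclei, 85 of them called C_PEP-like before, so these list medians depended on the border between the classes. Potassium and HCN channels (-0.19) then lay close to the -0.18 of all genes in the main clustering, and calcium channels (-0.10) and transcription factors (-0.0789) nearer 0 than it, so their difference was not kept.

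Each class was also set against all other named nuclei, to find what it transcribed most distinctly outside its own markers. C_PEP-like nuclei stood out by OPRK1 (22.0-fold higher, 13.9 to 36.6), the peptide gene GAL (148 against 9.33 CPM, 15.9-fold) and the bradykinin receptor gene BDKRB2 (9.79-fold), with KCNA1 12.2-fold and ONECUT1 11.9-fold lower. Low KCNA1 was shared by every C-fibre-like class (2.71 to 8.58 CPM, against 160 CPM in large-fibre-like nuclei). ONECUT1 stood at 2.81 CPM in C_PEP-like nuclei, 2.71 CPM in the GFRA2_LPAR3 class and 0.520 CPM in SST_OSMR-like nuclei. It was higher in C_TRPM8-like nuclei (28.1 CPM, 19.7 to 38.9) and highest in large-fibre-like nuclei (70.2 CPM). Over the alternatives the log2 ratios of C_PEP-like nuclei ran from 2.46 to 4.89 for OPRK1, 2.70 to 3.46 for BDKRB2, -3.99 to -2.02 for KCNA1 and -5.54 to -2.52 for ONECUT1, while that of GAL moved by less than 1.5 times. The GFRA2_LPAR3 class stood out by the T-type calcium channel gene CACNA1I (64.8 against 2.46 CPM, 26.4-fold, 17.9 to 40.0), POU4F2 (7.89-fold) and KCNH6 (7.56-fold), with KCNA1 20.5-fold and GAL 17.8-fold lower. The KCNA1 gap came mainly from large-fibre-like nuclei and the GAL gap mainly from C_PEP-like nuclei. GAL stood at 3.88 CPM in the GFRA2_LPAR3 class, and at 9.36 to 14.6 CPM in the classes other than C_PEP-like. For the GFRA2_LPAR3 class log2 ratios ran from 4.44 to 5.47 for CACNA1I, -4.74 to -3.04 for KCNA1 and -4.45 to -3.05 for GAL, while those of POU4F2 and KCNH6 moved by less than 1.5 times. C_TRPM8-like nuclei stood out by CACNB2, a calcium channel subunit (3292 against 519 CPM, 6.34-fold), by the glutamate receptor gene GRM3 (8.99-fold) and by PRDM8 (10.6-fold, 6.95 to 16.2). They had 20.7-fold less PIEZO2 (15.4 to 28.4) and 17.0-fold less DPP6 than all other named nuclei together. The GFRA2_LPAR3 class and large-fibre-like nuclei were highest, at 2067 and 929.8 CPM of PIEZO2 and 2701 and 2076 CPM of DPP6. SST_OSMR-like nuclei were much nearer, at 44.2 against 35.1 CPM of PIEZO2 and 129.5 against 75.6 CPM of DPP6. The log2 ratios of C_TRPM8-like nuclei ran from -4.84 to -2.94 for PIEZO2, -4.37 to -2.97 for DPP6, 2.26 to 3.67 for PRDM8 and 2.44 to 3.77 for GRM3 over the alternatives, and the value nearest 0 of each came with list genes kept in the clustering. That of CACNB2 moved by less than 1.5 times.

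Against all other named nuclei, SST_OSMR-like nuclei carried more NMB (14.3-fold), TRPC6 (10.4-fold) and NPY2R (8.66-fold), and KCNH1 was 26.7-fold lower. As means of within-library log2 ratios NMB went from 3.83 to 2.73 and TRPC6 from 3.38 to 4.65, so the order of these genes turned. ONECUT1 had 1 UMI in them against 344 (286 of these in large-fibre-like nuclei), with an interval of 8.89 to 1974. Its log2 ratio went from -5.64 to -3.41 without library 1 and to -1.01 with count splitting. KCNH1 went from -4.74 to -5.65 without library 6, and TRPC6 gave 4.09 without library 6. Over all alternatives log2 ratios ran from 2.68 to 4.12 for NMB, 1.88 to 4.90 for TRPC6, -6.51 to -1.01 for ONECUT1 and -6.25 to -1.37 for KCNH1, while that of NPY2R moved by less than 1.5 times. The large-fibre-like nuclei against the rest are the mirror of the comparison with C-fibre-like nuclei. For the named genes of these classes the direction was the same in every library with a value. The median log2 ratio of all genes was -0.22 for SST_OSMR-like and -0.22 for C_TRPM8-like nuclei, and between -0.09 and 0.04 for the other classes.

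A set of pain and itch genes fixed beforehand was read in every class. The sodium channel genes split the C-fibre-like classes. SCN9A was present in all, from 737 CPM in C_PEP-like to 1216 CPM in SST_OSMR-like nuclei, against 310 CPM in large-fibre-like ones. SCN10A stood at 702, 691 and 845 CPM in the C_PEP-like, SST_OSMR-like and GFRA2_LPAR3 classes but at 60.8 CPM (48.1 to 75.9) in C_TRPM8-like nuclei, an interval that overlaps that of large-fibre-like nuclei (70.2 CPM, 62.3 to 78.8). That overlap joins libraries that went opposite ways: SCN10A in C_TRPM8-like against large-fibre-like nuclei stood at 30.4 (16.6 to 51.0) against 75.9 CPM (60.3 to 94.2) in library 3, at 61.0 against 94.0 CPM in library 6 and at 161 (114.5 to 220) against 84.3 CPM (52.2 to 129) in library 5. SCN11A was highest in SST_OSMR-like nuclei (1024 CPM) and as low as 31.2 CPM in C_TRPM8-like nuclei. In libraries 3, 5 and 6, SCN10A and SCN11A were lower in C_TRPM8-like nuclei than in each of the other 3 C-fibre-like classes.

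PIEZO2 was highest in the GFRA2_LPAR3 class, at 2067 CPM (2012 to 2123), above the 929.8 CPM of large-fibre-like nuclei, but in library 5 these stood at 2412 and 2465 CPM. It was low in SST_OSMR-like (44.2 CPM) and C_TRPM8-like nuclei (35.1 CPM). TRPV1 was rare throughout, at 103 CPM in C_TRPM8-like, 40.1 CPM in C_PEP-like and 30.7 CPM in SST_OSMR-like nuclei against 2.70 CPM in large-fibre-like nuclei. A single deep nucleus held 28.0% of the TRPV1 UMIs of the C_TRPM8-like class, which stood at 78.2 CPM without it. That nucleus held 0 of the 984 TRPM8 UMIs and 0 of the 527 TAC1 UMIs of its class, both naming markers. TRPA1 peaked in C_PEP-like nuclei at 176.5 CPM, against 40.6 to 67.8 CPM elsewhere, but in library 4 it stood at 79.2 CPM there and at 96.1 CPM in large-fibre-like nuclei. TRPM8, a marker, stood at 86.2 CPM in C_PEP-like nuclei, or 53.2 CPM without their deepest nucleus.

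The mu opioid receptor gene OPRM1 stood at 660 CPM in SST_OSMR-like and 331 CPM in C_PEP-like nuclei, against 49.2 CPM in the GFRA2_LPAR3 class and 44.0 CPM in large-fibre-like nuclei. One library 2 nucleus with 269590 UMIs held 35.2% of the OPRM1 UMIs of the SST_OSMR-like class, which stood at 498 CPM without it. Library 1 had 901 against 518 CPM, but OPRM1 stood at 163 against 182 CPM in library 3, 377 against 326 CPM in library 5 and 356 against 362 CPM in library 6, so the pooled gap between these classes did not hold across libraries. The same nucleus held 60.4% of the SST UMIs of that class. SST itself was a rare transcript: 105 CPM in SST_OSMR-like nuclei (91.1 to 121), 48.4 CPM without that nucleus, and 107 CPM in library 1 against 20.6 CPM in library 3. OSMR stood at 525 CPM in SST_OSMR-like nuclei and at 151 CPM in the GFRA2_LPAR3 class. TAC1 was high in SST_OSMR-like (4119 CPM) and C_PEP-like nuclei (2475 CPM). It ranged from 439 CPM in library 6 to 6226 CPM in library 1 in the former and from 549 CPM in library 6 to 8558 CPM in library 4 in the latter. In libraries 1, 5 and 6 it was lower in SST_OSMR-like than in C_PEP-like nuclei. CHRNA3 was scarcely detected, from 45 UMIs in large-fibre-like nuclei to 0 UMIs in C_TRPM8-like nuclei. For that 0 the floor of 3 counts is 2.34 CPM and the exact upper limit 2.88 CPM.

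**Figure D4:**
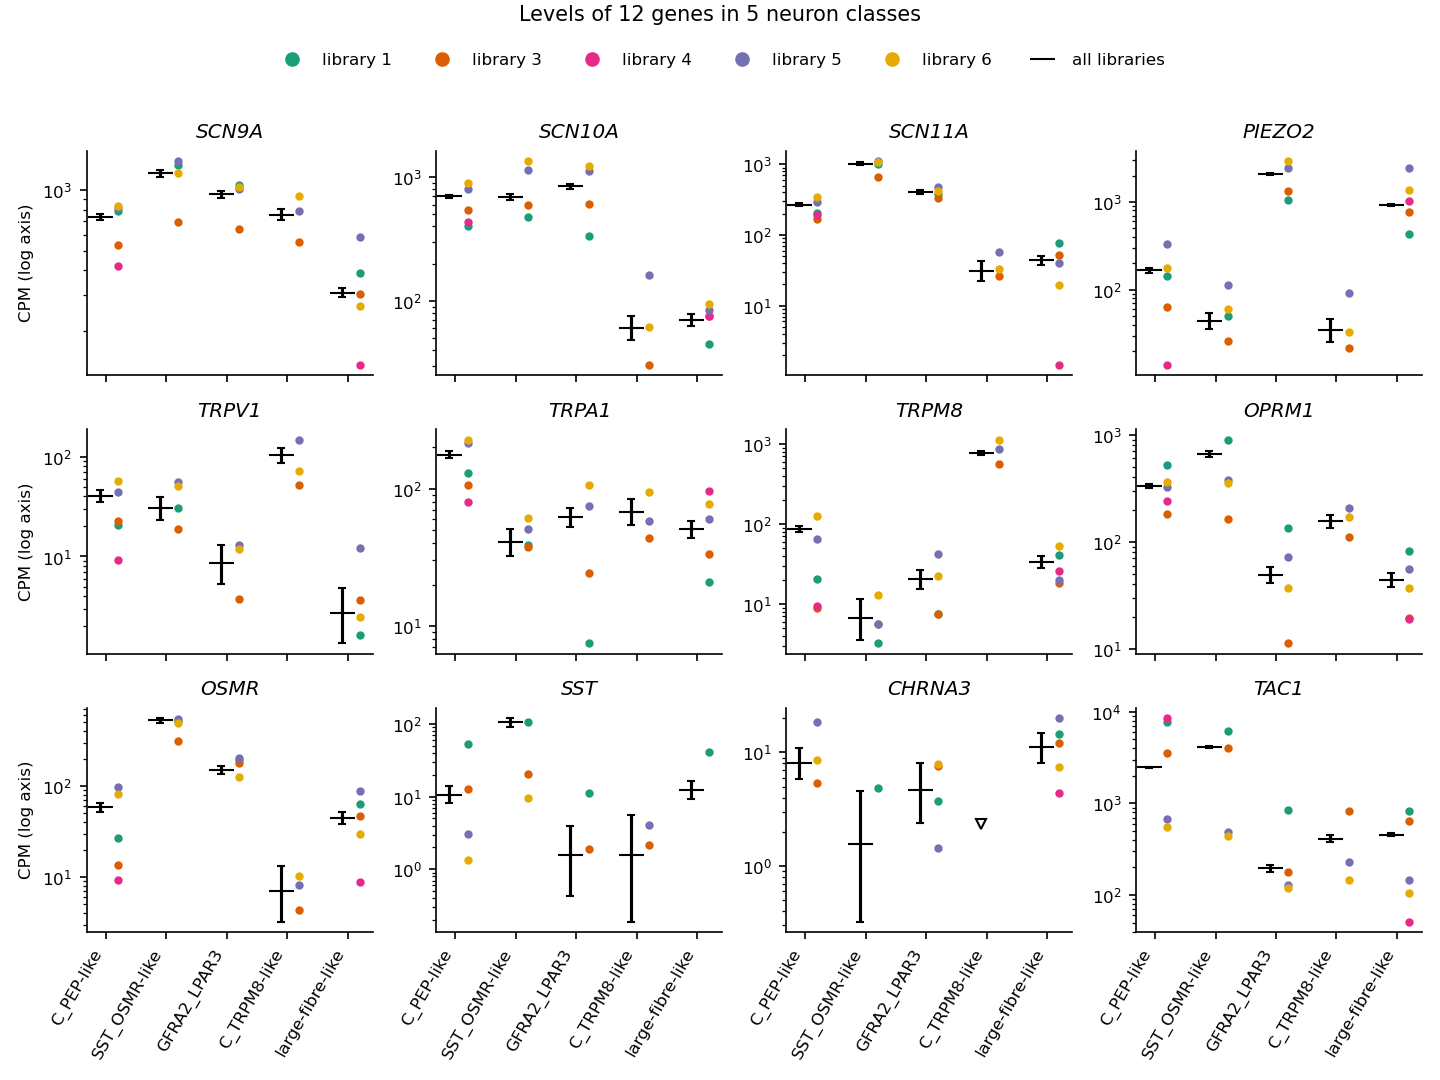
CPM (log axis) of 12 genes in the 5 neuron classes, with all libraries and exact 95% Poisson intervals in black and single libraries in colour. Libraries at 0 UMIs or with under 10 nuclei of a class are not drawn. The open triangle is the floor of 3 counts set for a count of 0. PIEZO2 reached 2067 CPM in the GFRA2_LPAR3 class, and SCN10A stood at 60.8 CPM in C_TRPM8-like nuclei.

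Transcripts of other ganglion cells were read over the whole table from marker lists. The lists summed to 876.5 CPM for satellite glia, 466 CPM for myelinating Schwann cells and 175 CPM for fibroblasts. They summed to 90.9 CPM for endothelium, 75.1 CPM for adipocytes, 67.2 CPM for lymphocytes, 49.3 CPM for erythroid cells, 36.1 CPM for macrophages and 28.5 CPM for mural cells. The list for non-myelinating Schwann cells summed to 1502 CPM and reached 2455 CPM in the GFRA2_LPAR3 class, where its members NRXN3 and SCN7A alone stood at 1554 and 697 CPM, against 8.53 CPM of the glial gene SOX10. Satellite glia transcripts were higher in library 1 (2376 CPM) than in libraries 5 and 6 (298 and 278 CPM). One cluster of 21 nuclei, all from library 4, scored highest for the fibroblast markers and stayed unnamed.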

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

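The alternatives that leave out a library or the deepest nuclei, average within libraries, drop mitochondrial genes from CPM, cluster libraries alone or lower the naming score were chosen after seeing the data; the others were fixed before. A share or list median counts as moved when it left its 95% interval, which for a list median is an interval over its genes. Where no reason is given the cause was not tested. Ratios of named genes left their counting interval in 135 of 344 cases under the settings that draw the clusters again: 30 of 60 with list genes kept, 21 of 60 at resolution 0.5, 28 of 60 at resolution 1.5, 9 of 60 with at least 1000 genes, 17 of 48 with count splitting and 30 of 56 with each library clustered alone. Under the other settings they left it in 21 of 26 cases after thinning, 17 of 60 as mean CPM over nuclei, 22 of 60 as means of within-library ratios, 9 of 60 at a naming score of 0.5, 12 of 56 without library 6, 9 of 59 without library 1 and 7 of 58 without nuclei above 50000 UMIs, and in 5 or fewer cases in each other setting that could move them. The minimum of 10 UMIs cannot move a ratio already named. All kept their sign but 1, P2RX5 in SST_OSMR-like over other C-fibre-like nuclei (-0.62 with count splitting). The ratios below are median log2 ratios, C/large for C-fibre-like over large-fibre-like and SST/C for SST_OSMR-like over other C-fibre-like nuclei.

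With list genes kept in the clustering, shares were 22.8% C_PEP-like, 12.1% SST_OSMR-like, 19.0% C_TRPM8-like and 18.9% large-fibre-like. SST/C was then -0.30 for potassium and HCN channels, -0.105 for calcium channels, 0.00168 for transduction channels, 0.14 for ligand-gated channels, -0.0885 for pronociceptive receptors, 0.0202 for cytokine receptors, -0.0504 for transcription factors and -0.28 for the mitochondrial genome, for which C/large was 0.58. At resolution 1.5, shares were 21.8% C_PEP-like, 13.1% SST_OSMR-like and 21.0% large-fibre-like, and SST/C in the same order of lists was -0.19, -0.10, 0.0466, 0.000419, 0.0871, 0.0944, -0.0789 and -0.33. In these settings 75 and 85 C_PEP-like nuclei, 73 and 84 of them from libraries 5 and 6, entered the SST_OSMR-like class. At resolution 0.5, shares were 43.4% C_PEP-like, 7.17% SST_OSMR-like, 8.45% GFRA2_LPAR3 and 17.1% large-fibre-like, C/large was 0.49 for injury genes and SST/C was 1.31 for the mitochondrial genome. With each library clustered alone, shares were 18.8% C_PEP-like, 10.7% SST_OSMR-like, 7.81% C_TRPM8-like and 14.8% large-fibre-like; C/large was 0.32 for injury genes and -0.28 for the mitochondrial genome, and SST/C was -0.30 for transcription factors and 0.16 for the mitochondrial genome. Of 1273 nuclei named both ways, 93.6% kept their class. A naming score of 0.5 raised the C_TRPM8-like share to 23.4%, by its construction, since it admits the cluster of 302 nuclei.

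With at least 1000 genes per nucleus, shares were 37.8% C_PEP-like, 11.8% GFRA2_LPAR3, 7.88% C_TRPM8-like and 17.3% large-fibre-like, and C/large was 0.89 for the mitochondrial genome. With count splitting, shares were 20.01% C_PEP-like, 2.74% SST_OSMR-like, 8.36% GFRA2_LPAR3 and 17.6% large-fibre-like; C/large was -0.935 for injury genes and 1.14 for the mitochondrial genome, and SST/C 2.02 for the latter. Thinning to 1000 UMIs gave C/large of 0.97 for pronociceptive receptors and -0.86 for injury genes, and SST/C of 0.31 for the mitochondrial genome, which was 0.29 as mean CPM over nuclei. Thinning left out 78 shallower nuclei of named classes and gave no value for genes then below 50 UMIs.

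Without library 1, shares were 32.6% C_PEP-like, 12.3% GFRA2_LPAR3 and 13.6% C_TRPM8-like. Without library 3, they were 6.07% C_TRPM8-like and 19.4% large-fibre-like. Without library 5, they were 23.8% C_PEP-like, 7.37% GFRA2_LPAR3 and 26.7% large-fibre-like, and without library 6, 24.8% C_PEP-like. For the mitochondrial genome, C/large was 0.32, -0.28, 0.00291, 0.44 and 0.50 without libraries 1, 3, 4, 5 and 6, 0.0310 without nuclei above 50000 UMIs and 0.96 as a mean of within-library values. SST/C was 1.12, 1.32, 0.65 and 0.43 without libraries 1, 3, 5 and 6, 0.63 without those nuclei and 0.21 as a mean of within-library values.

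No paired analysis was possible because nuclei were not tied to pigs. For that reason edgeR, DESeq2, leaving out pigs, a minimum of 20 nuclei per pig, integration over pigs and set tests with an estimated correlation were not run, and keeping called doublets was not a separate setting, since none had been removed. Depth limits the genes with 1 to 5 UMIs on a side.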

Other observations

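Of the tests below, the comparison of SST within library 1 and the split of library 1 by depth were chosen only after the result was seen, and the groups of clusters described first were chosen after their genes were seen.

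Nuclei that took no class name still had distinct list genes. A pair of clusters led by CDH13 and SORCS3, 99 nuclei from libraries 1, 3, 4, 5 and 6, stood out from all named nuclei by the receptor tyrosine kinase gene KIT (568 against 56.1 CPM, 10.1-fold, counting interval 9.08 to 11.3). They also carried more of the peptide gene CARTPT (16.4-fold, 12.3 to 22.0), the muscarinic receptor gene CHRM2 (9.89-fold, 7.24 to 13.4), TRPC5 (7.88-fold) and the potassium channel gene KCNQ5 (2698 against 411 CPM). Another cluster of 34 nuclei, mostly from libraries 3 and 6, shared high KIT (759 CPM) and KCNQ5 (4110 CPM) with them. Against all named nuclei it also carried more KCNC2 (1273 against 126 CPM, 10.1-fold), TRPC4 (9.67-fold), KCNK10 (8.96-fold) and NTRK2 (1337 against 224 CPM). Within each library that gave a value these ratios lay on the same side of 1.

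SST transcripts in SST_OSMR-like nuclei stood at 107 CPM in library 1 against 6.13 CPM (3 UMIs, 1.26 to 17.9) in libraries 5 and 6 together, and NMB followed (1912 against 79.7 CPM) but OSMR did not (512 against 515 CPM). Other classes rose too: SST stood at 52.2 against 1.87 CPM in C_PEP-like nuclei and at 41.3 CPM against 0 UMIs in large-fibre-like nuclei, where NMB stood at 201.5 against 0.946 CPM. More cytoplasmic RNA kept with the nuclei of library 1 is a candidate explanation, since ribosomal protein transcripts were higher in SST_OSMR-like nuclei there by a median log2 ratio of 2.91 over 44 genes. Free RNA could raise those transcripts too, so they do not tell these causes apart. In SST_OSMR-like nuclei satellite glia markers summed to 1776 CPM in library 1 against 242 and 173 CPM in libraries 5 and 6. Erythroid markers summed to 126 against 16.9 and 12.8 CPM, and myelinating Schwann cell markers to 1261 against 208 and 317.5 CPM. The fibroblast, mural, adipocyte and non-myelinating Schwann cell lists were also above both libraries. The endothelial, macrophage and lymphocyte lists were not. Free RNA stays open. Within library 1 SST was higher in SST_OSMR-like than in the other named nuclei by a log2 ratio of 1.41 (0.93 to 1.89), but SST helped to name that class, so this test decides nothing. Differences between pigs or isolation protocols stay open as well, and no biological explanation was tested.

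The 254 large-fibre-like nuclei of library 3 fell into clusters led by HS3ST4 (95 nuclei, not tested here), by NEFH (88 nuclei, median mitochondrial share 26.9%) and by FRMPD4 (71 nuclei, 0.861%). If cytoplasmic RNA on nuclei of 1 type had parted the NEFH-led from the FRMPD4-led cluster, C-fibre-like nuclei of the same library should differ alike between high and low mitochondrial shares (limits set when the test was coded). Over the 80 list genes at least 4-fold apart, the median signed log2 ratio was 1.03 there (0.76 to 1.17, an interval over genes) against 3.11 between these clusters, which lies between the bounds predicted for that cause and against it. Cytoplasmic RNA and a difference in cell type cannot be told apart here, and no biological explanation was tested.

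Of the nuclei of library 1, 46.9% took no name (320 nuclei). Among those at or above its median of 2647 UMIs 13.2% were unnamed (9.79 to 17.3%), against 80.7% below it (76.1 to 84.7%). Names were given by cluster and 296 of these nuclei formed 1 shallow cluster, so this split restates its depth and decides nothing. That cluster scored 0.722 for the C_TRPM8 markers, just under the limit of 0.75 that was set after the data were seen, and takes that name at 0.5. Shallow nuclei and a shallower cell type cannot be told apart here, and no biological explanation was tested.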
